A study of Juglans cathayensis with 6 samples.

How the data were processed

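Husk of *Juglans cathayensis* was profiled by RNA sequencing in 6 libraries, 3 from a variety whose freshly cut husk is recorded as white and 3 from a variety whose freshly cut husk is recorded as brown. All 6 carry a time label of 35 days, and the labels do not state from which event the days were counted. RNA was extracted with the MiniBEST Plant RNA Extraction Kit and made into Illumina libraries, per the labels' protocols. Reads were handled with cutadapt and FastQC, per the submitters' processing notes, which give no versions. Transcripts were assembled with Trinity, as the gene identifiers deposited by the authors show, since every identifier carries that program's name. The quantifier, its settings and the database versions behind the annotation are not given in the sources used here.

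The table deposited by the authors gives TPM (a length-normalized relative abundance) for each assembled gene in each library, with gene length, protein descriptions, GO terms and KEGG pathways. It lists 39234 genes, and the lowest value that a gene reaches in its highest library is 2.01 TPM, so the table holds only genes above a minimum. Columns add up to between 994877 and 996692 TPM, and TPM keeps no read depth, so the depth of each library is unknown and no counting interval or detection floor can be given. Of the listed genes, 24054 have a description in the main annotation column, of which 22263 come from *Juglans regia*, the common walnut, and 15584 have a Swiss-Prot description. The main description was used as the name of a gene where it names a protein, and the Swiss-Prot description otherwise. No genome of the species was used here, so genes are identified by assembly identifier only. An assembled gene can be 1 allele or part of 1 member of a gene family, and reads shared between near-identical copies can be split between them. The TPM of a single member of a large family is therefore uncertain.

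Samples were grouped by the colour given in their labels. Replicate numbers are not stated to mark a shared tree, batch or day, and no label says that libraries of a group came from separate trees. P-values then measure only the spread between these samples, which may be technical. TPM values were transformed as log2(TPM + 1), and genes with at least 1 TPM in at least 3 of the 6 libraries were tested, which left 37829. Brown was compared with white by limma with a mean-variance trend, without covariates, and p-values were adjusted by the Benjamini-Hochberg method. Genes with an adjusted p under 0.05 are said to have risen or fallen, and log2 fold changes are brown minus white on the log2(TPM + 1) scale, which understates the change of low genes. Counts are also given with a fitted fold of at least 2.

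The 32 gene lists were written as text patterns before the data were examined, and a gene belongs to a list when either of its descriptions matches. Lists with at least 5 tested members, 30 in all, were tested with camera (preset inter-gene correlation of 0.01), with an estimated correlation and with fry beside it. Camera compares the moderated test statistics of a list, not its fold changes, with those of all other tested genes. The mean log2 fold change of all tested genes was 0.22. Camera placed 12 lists with a positive mean and median below the other genes, and their direction by camera is not a fall in TPM. GO terms and KEGG pathways of 10 to 500 tested genes were tested by a one-sided Fisher's exact test against tested genes with at least 1 term. Genes at 0 TPM in all 3 libraries of a group and at 1 TPM or more in all 3 of the other were counted. Library measures were compared by an exact two-sided permutation test, for which 0.1 is the smallest p that 3 against 3 can give. Named genes were taken by a rule fixed before the data were examined. It takes the 10 largest rises and the 10 largest falls among genes past the threshold with non-overlapping groups, a mean of at least 10 TPM in the higher group and a naming description, each description once. It also takes up to 3 members past the threshold with the highest mean TPM in each list. For polyphenol oxidase, class III peroxidase, laccase and phenylpropanoid entry genes it adds the 3 members with the highest mean TPM whether past the threshold or not.

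The fit was tested on simulated data for this comparison, over 37829 genes with 200 of them changed. It recovered 10.4% of genes changed by a log2 fold of 1, 67.2% of those changed by 2 and 92.4% of those changed by 3, and called 8 unchanged genes among 121 calls. The changed genes were drawn only from those with a mean log2(TPM + 1) above that of 5 TPM. Noise was drawn independently for each gene from the fitted mean-variance trend. Changes in low genes and genes that vary together were thus not covered, and these rates need not hold for the real data. Alternatives were other pseudocounts (0.1 and 0.5), no filter, a filter of 5 TPM, TMM factors, quantile normalization, no trend, array weights, the replicate number as a block, and each library left out in turn. TMM factors were computed on TPM with 30% trimmed from the ratios and 5% from the means. Array weights stopped before full convergence. Alternatives chosen after seeing the data were matching in both descriptions, a WRKY list without disease resistance proteins, leaving out the second library of both groups, and 4 further gene lists. R 4.3.3 with limma 3.58.1 and Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9 were used.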

Results

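RNA was sequenced from husk, the fleshy outer layer of the fruit, of *Juglans cathayensis*, the Chinese walnut. The series compares 2 varieties that differ in the colour of the freshly cut husk, white or brown, to learn about enzymatic browning, the oxidation of phenolic compounds to dark pigments after cells are cut. Because each colour comes from a different variety, no difference reported here can be tied to colour rather than to another difference between the varieties. Each variety had 3 libraries. At 1 TPM or more, white replicates 1, 2 and 3 held 33949, 28349 and 33146 genes, and brown replicates 1, 2 and 3 held 34826, 35240 and 35196. The means were 31815 ± 3028 genes in white and 35087 ± 227 in brown husk (SD, n = 3 each, exact two-sided permutation p = 0.1, the smallest that 3 against 3 can give). White replicate 2 stood apart from the other white libraries, and without it the difference of 3273 genes became 1540. In that library the 100 highest genes took 34.0% of TPM, against 24.7% and 27.2% in white replicates 1 and 3 and 26.0% to 26.5% in the brown libraries. The share of the 100 highest genes was 28.6% ± 4.78 in white and 26.3% ± 0.254 in brown husk (SD, n = 3 each, exact two-sided permutation p = 0.7). Spearman correlations across genes, which are not independent replicates, were 0.789 to 0.846 between libraries of a group and 0.693 to 0.748 between libraries of different groups.

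In brown husk 24 of 119 pathogenesis-related genes rose, chitinases and glucanases among them, as did 13 of 69 WRKY and 16 of 85 ERF transcription factors. Of these lists WRKY factors alone were past the threshold by camera, and not with an estimated correlation (adjusted p = 0.942). Rises were also found for 1 polyphenol oxidase, 3 class III peroxidase, 1 laccase and 1 phenylalanine ammonia-lyase gene. In the other direction 9 of 89 heat shock genes, 3 alpha tubulins and 9 of 270 cytosolic ribosomal protein genes fell, while 3 heat shock and 2 ribosomal protein genes rose. The ribosomal protein list was not past the threshold by camera (adjusted p = 0.359), and its mean log2 fold change was positive, at 0.07. Of 37829 genes tested, 1450 were higher and 819 lower in brown husk at an adjusted p under 0.05 (limma, Benjamini-Hochberg), and 1326 and 663 of these had a fitted fold of at least 2. The balance of directions depended on scaling, with 1322 higher and 1225 lower under TMM factors and 1259 higher and 1275 lower under quantile normalization. The median log2 fold change of all tested genes was 0.19 as deposited, 0.02 with TMM factors and -0.01 with quantile normalization. Log2 fold changes given here were not corrected for that median, and whether it comes from scaling or from expression cannot be told here. All 2269 genes kept their sign in every alternative that tested them, but those fits reuse the libraries on which the genes were selected. The counts fell to 495 higher and 262 lower without white replicate 3, to 924 and 425 without brown replicate 1, to 550 and 318 without brown replicate 2, and to 410 and 259 without brown replicate 3, and the lower count fell to 501 without white replicate 1. Of the 87 genes named by rule that passed the threshold, 33 passed it in each of the 6 fits that left out 1 library, and 64, 69 and 37 did so without white replicates 1, 2 and 3 and 52, 39 and 33 without brown replicates 1, 2 and 3.

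**Figure D1:**
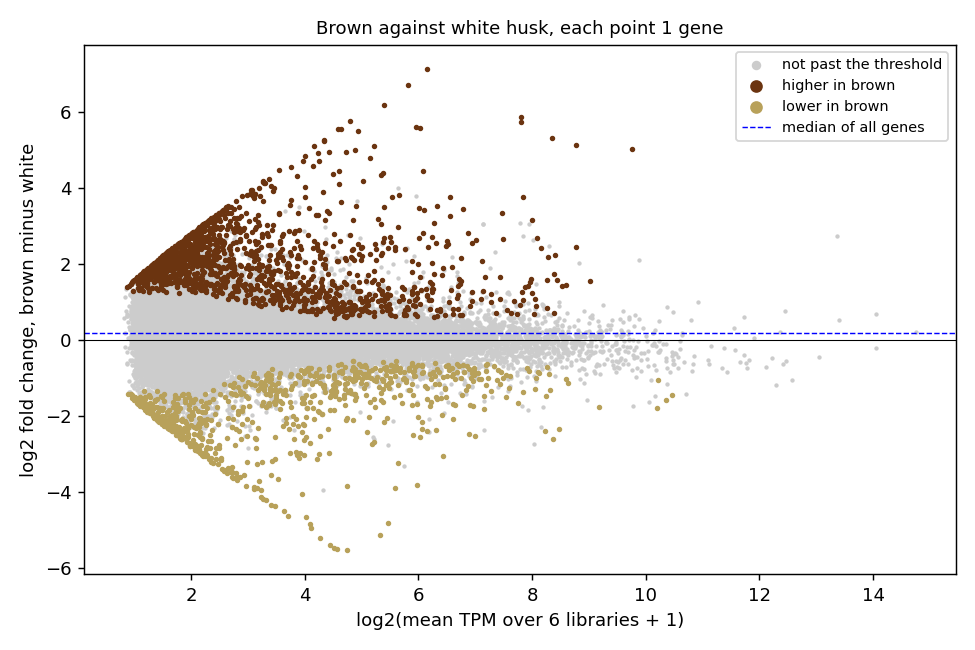
Each point is 1 tested gene, with log2 of its mean TPM over the 6 libraries plus 1 on the horizontal axis and its log2 fold change, brown minus white, on the vertical axis. Brown points are the 1450 genes that were higher and tan points the 819 that were lower in brown husk, and the dashed line is the median of all tested genes at 0.19.

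Among the 10 largest rises were 4 genes matched to secreted proteins. A basic glucan endo-1,3-beta-glucosidase (TRINITY_DN14834_c1_g3), an enzyme that cuts the beta-glucans of fungal walls, had 22.1 ± 11.6 TPM in white and 854 ± 523 TPM in brown husk (SD, n = 3 each), a log2 fold change of 5.15 ± 0.56 (SE, limma adjusted p = 0.00409). A P21-like protein (TRINITY_DN14626_c0_g1), of the thaumatin family, had 11.9 ± 4.65 and 637 ± 467 TPM. A gene matched to a basic secretory protease (TRINITY_DN4519_c0_g1) had 38.8 ± 2.60 and 1699 ± 1312 TPM, and an EG45-like domain protein (TRINITY_DN8584_c0_g1) had 0.89 ± 0.471 and 121 ± 104 TPM. For these 4 genes brown replicate 2 was the highest and brown replicate 1 the lowest of the brown libraries, and all 4 passed the threshold in each of the 6 fits that left out 1 library. Receptor-like kinases made up 3 of the largest rises. The kinase matched to At4g00960 (TRINITY_DN14518_c2_g2) had 0.0267 ± 0.0252 TPM in white and 48.0 ± 6.0 TPM in brown husk. A partial At3g14840-like kinase (TRINITY_DN13436_c0_g1) had 0.83 ± 0.442 and 56.4 ± 5.62 TPM. Another At3g14840-like kinase (TRINITY_DN16062_c3_g3) was listed at 0 in all 3 white libraries and at 53.7, 25.5 and 36.8 TPM in the brown ones. The remaining rises were a neomenthol dehydrogenase-like gene (TRINITY_DN14724_c0_g3), with 0.0133 ± 0.0231 and 34.1 ± 4.55 TPM, and 2 genes like UPF0481 protein At3g47200. The first of these (TRINITY_DN12717_c1_g2) was listed at 0 in the white libraries and at 56.4, 51.3 and 53.6 TPM in the brown ones, and the second (TRINITY_DN12406_c0_g5) at 0 and at 42.2, 46.5 and 26.7 TPM.

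Among the 10 largest falls, 4 genes had transcript in both groups. An AGL9-like gene (TRINITY_DN14521_c0_g1), a MADS-box transcription factor of a family that patterns flowers and fruits, had 115 ± 56.6 TPM in white and 7.91 ± 5.76 TPM in brown husk, a log2 fold change of -3.81 ± 0.59 (SE, limma adjusted p = 0.0139, not past the threshold without white replicate 3 or brown replicate 3). A gene matched to a viral enzymatic polyprotein (TRINITY_DN16004_c0_g1), a protein of caulimoviruses that related sequences in plant genomes also encode, had 76.8 ± 4.10 and 1.25 ± 0.291 TPM (log2 fold change -5.12 ± 0.17, adjusted p = 5.2e-05). A gene for STS14 protein (TRINITY_DN16763_c0_g1) had 49.2 ± 17.7 and 2.49 ± 0.974 TPM, and a 40S ribosomal protein S5-like gene (TRINITY_DN13559_c0_g1) 31.9 ± 2.25 and 0.15 ± 0.195 TPM. The genes listed at 0 in all 3 brown libraries included one for mitochondrial aminomethyltransferase (TRINITY_DN14845_c1_g5), at 52.9, 33.6 and 44.8 TPM in white husk, and a metal transporter Nramp5-like gene (TRINITY_DN12620_c1_g10), at 31.0, 18.2 and 22.9 TPM. They also included alpha-mannosidase I MNS4 (TRINITY_DN12176_c0_g1), at 13.3, 10.2 and 10.7 TPM, and an elastin-like gene (TRINITY_DN4131_c0_g1), at 7.18, 22.0 and 8.27 TPM. An At3g14840-like kinase (TRINITY_DN13113_c0_g3) and a UPF0481-like gene (TRINITY_DN12717_c1_g3) had descriptions that also occur among the rises. The latter was listed at 21.1, 11.6 and 21.5 TPM in white and at 0 in brown husk, and shares its assembly cluster with the UPF0481-like gene that rose. Of the 93 genes named by rule, 16 shared their cluster with at least 1 gene past the threshold in the opposite direction. Besides the UPF0481-like pair these included the AGL9-like gene (2 such cluster members) and, with 1 each, the aminomethyltransferase gene, the kinase TRINITY_DN16062_c3_g3, peroxidase 73-like (TRINITY_DN15585_c2_g1), ERF106-like (TRINITY_DN15528_c3_g2) and the 40S protein S16-like gene (TRINITY_DN13882_c2_g1). Assembled genes with such close relatives cannot be separated from alleles of 1 locus here.

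Among browning enzymes, polyphenol oxidase is the copper enzyme that oxidizes phenolics to quinones. Of its 2 tested genes 1 rose, and both did when p-values were adjusted over the list alone. The gene TRINITY_DN12255_c0_g1 had 27.9 ± 7.12 TPM in white and 121 ± 42 TPM in brown husk (SD, n = 3 each), a log2 fold change of 2.04 ± 0.30 (SE, limma adjusted p = 0.0110), and missed the threshold without brown replicate 3. The other gene, TRINITY_DN12255_c0_g2, had 0.737 ± 0.549 and 27.2 ± 23.3 TPM and an adjusted p of 0.0501. Of 31 class III peroxidases, secreted enzymes that oxidize phenolics with hydrogen peroxide, 3 rose and none fell, with 9 higher and 2 lower when adjusted over the list alone, and the list was not past the threshold by camera (adjusted p = 0.285). Peroxidase 73-like (TRINITY_DN15585_c2_g1) had 151 ± 23.3 and 514 ± 119 TPM (log2 fold change 1.74 ± 0.22, adjusted p = 0.00698) and passed in each fit that left out 1 library. Peroxidase 27-like (TRINITY_DN2854_c0_g1) had 137 ± 7.98 and 240 ± 11.9 TPM, and cationic peroxidase 1-like (TRINITY_DN10961_c0_g1) 0.62 ± 0.510 and 29.4 ± 24.7 TPM. Peroxidase 27-like missed the threshold without white replicate 3 or any 1 brown library, and cationic peroxidase 1-like when any library other than brown replicate 1 was left out. Peroxidase 42 (TRINITY_DN8623_c0_g1), with 101 ± 46.6 and 227 ± 18.5 TPM, had an adjusted p of 0.0626. Without brown replicate 1 the list passed by camera with 7 members higher (adjusted p = 0.0126, or adjusted p = 0.977 with an estimated correlation), and 1 member rose without white replicate 3, brown replicate 2 or brown replicate 3. Of 7 laccases 1 rose, also when adjusted over the list alone, laccase-15-like (TRINITY_DN15107_c2_g3), from 0.463 ± 0.409 to 11.5 ± 5.28 TPM. The most abundant laccase, laccase-14-like (TRINITY_DN15107_c2_g7), had 86.8 ± 83.7 and 38.6 ± 26.5 TPM (adjusted p = 0.684).

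**Figure D2:**
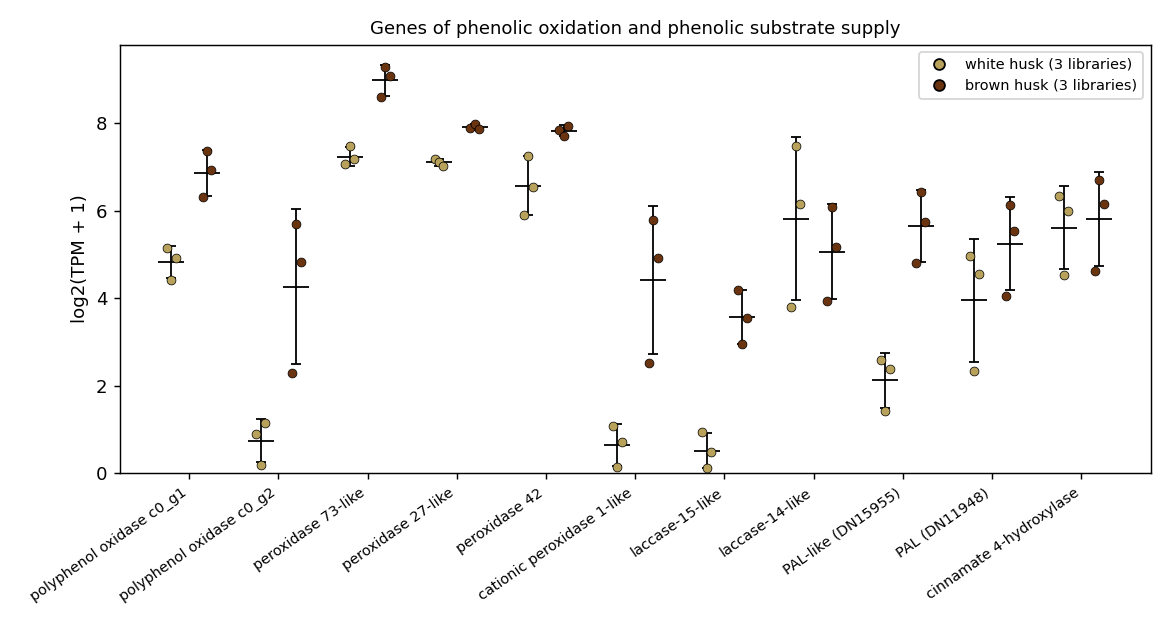
The vertical axis gives log2(TPM + 1) for 11 genes of phenolic oxidation and phenolic supply along the horizontal axis, with 1 point per library, tan for white and brown for brown husk, and bars for the mean and SD of the 3 log2 values. Polyphenol oxidase c0_g1, peroxidase 73-like, peroxidase 27-like, laccase-15-like and the PAL-like gene DN15955 show no overlap between groups, while laccase-14-like, PAL DN11948 and cinnamate 4-hydroxylase overlap.

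Genes that supply phenolic substrates were tested in 6 lists. Of 11 genes at the entry of phenylpropanoid synthesis 1 rose, and 3 did when adjusted over the list alone (camera adjusted p = 0.285). In that list 6 genes had an unadjusted p under 0.05 by limma, 9 had a positive log2 fold change, and the median was 0.92 against 0.19 for all genes. The median was 0.49 against 0.06 without white replicate 2, where 1 gene rose and 1 fell. It was 0.20 against 0.06 without the second library of both groups. Without brown replicate 1 the list passed by camera (adjusted p = 0.0322, or adjusted p = 0.977 with an estimated correlation). A phenylalanine ammonia-lyase-like gene (TRINITY_DN15955_c0_g1), of the enzyme that opens the pathway, rose from 3.61 ± 1.75 to 54.6 ± 29.2 TPM (log2 fold change 3.53 ± 0.46, limma adjusted p = 0.00789) and passed in each fit that left out 1 library. A second phenylalanine ammonia-lyase (TRINITY_DN11948_c0_g1) had 18.8 ± 13.4 and 43.2 ± 26.6 TPM (adjusted p = 0.379), and cinnamate 4-hydroxylase (TRINITY_DN14226_c0_g1) 54.6 ± 29.5 and 65.2 ± 39.5 TPM (adjusted p = 0.882). In the shikimate pathway 1 of 30 genes rose and 1 fell, the same numbers as when adjusted over the list alone. A 2-dehydro-3-deoxyphosphoheptonate aldolase (TRINITY_DN15205_c1_g5), of its first step, went from 4.86 ± 1.94 to 34.4 ± 14.9 TPM, though not past the threshold without brown replicate 2 or 3. The gene that fell, a probable inactive shikimate kinase (TRINITY_DN13695_c1_g2), lost its call without white replicate 1 or 3 or brown replicate 2 or 3. Of 45 genes of flavonoid and condensed tannin synthesis 1 rose and 2 fell (6 and 3 when adjusted over the list alone), and 12 had an unadjusted p under 0.05. A chalcone synthase-like gene (TRINITY_DN447_c0_g1) rose from 1.48 ± 1.18 to 26.1 ± 16.9 TPM, a call lost without white replicate 2 or 3 or brown replicate 2 or 3. An anthocyanidin 3-O-glucosyltransferase 5-like gene (TRINITY_DN15393_c2_g7) fell from 19.8 ± 0.760 to 3.56 ± 0.208 TPM. In the lignin branch 2 of 44 genes rose and 2 fell (2 and 3 adjusted over the list alone), all 4 of them caffeic acid O-methyltransferase-like, and 13 had an unadjusted p under 0.05. Without white replicate 2 the lignin branch had 3 rises and 4 falls, and without any other 1 library no rise. Of 69 genes for tannin-related acyl and glucosyl transfer 3 rose and 1 fell (3 and 2 adjusted over the list alone), and none passed without white replicate 3 or brown replicate 3 while 1 rose without white replicate 2 or brown replicate 2. None of 9 genes of naphthoquinone precursor synthesis, the branch towards juglone, the quinone of walnut husk, passed over all genes or over the list alone by limma, and 1 had an unadjusted p under 0.05.

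Pathogenesis-related genes, which include chitinases, glucanases, thaumatin-like proteins and PR-1, had 24 of 119 tested members higher and 3 lower in brown husk, and 30 and 6 when adjusted over the list alone. Their mean log2 fold change was 0.74 against 0.22 for all genes, and the list was not past the threshold by camera (p = 0.0198, adjusted p = 0.119, or adjusted p = 0.942 with an estimated correlation). It was past it without brown replicate 1 (adjusted p = 0.00181, 29 members higher) and with a filter of 5 TPM (adjusted p = 0.00118), but with an estimated correlation in neither (adjusted p = 0.977 and 0.997). Thaumatin-like protein 1 (TRINITY_DN15053_c0_g7) had 172 ± 29.5 TPM in white and 520 ± 102 TPM in brown husk (SD, n = 3 each, log2 fold change 1.58 ± 0.21, limma adjusted p = 0.00885). The number that rose was 11 without white replicate 3, 11 without brown replicate 2 and 9 without brown replicate 3, while 22 rose under both TMM factors and quantile normalization. The list median under quantile normalization was -0.01, against a mean of 0.52. WRKY transcription factors, many of which regulate defence genes, had 13 of 69 members higher and none lower, and 26 and none when adjusted over the list alone. The list was past the threshold by camera (adjusted p = 5.5e-05) but not with an estimated correlation (adjusted p = 0.942). WRKY 65 (TRINITY_DN13262_c1_g9) rose from 3.25 ± 0.219 to 15.5 ± 2.69 TPM, WRKY 40 (TRINITY_DN13259_c0_g7) from 4.64 ± 3.15 to 30.6 ± 16.6 TPM, and WRKY 48 (TRINITY_DN12763_c1_g4) from 17.0 ± 0.185 to 30.7 ± 4.95 TPM. The call of WRKY 40 was lost without white replicate 2 or 3 or brown replicate 2 or 3, and that of WRKY 48 when any library other than white replicate 2 was left out. With white replicate 1, white replicate 3, brown replicate 2 or brown replicate 3 left out, 8, 2, 3 and 2 WRKY genes rose, and 8 did with array weights. With the replicate number as a block 3 WRKY genes rose. Of 85 ERF factors, a family that responds to ethylene and stress, 16 rose and 1 fell (21 and 3 adjusted over the list alone, camera adjusted p = 0.285), with 12 and 4 under TMM factors and 11 and 4 under quantile normalization. ERF106-like (TRINITY_DN15528_c3_g2) rose from 54.8 ± 8.12 to 157 ± 35.2 TPM, and ERF105-like (TRINITY_DN14783_c0_g6) from 87.3 ± 16.7 to 186 ± 26.9 TPM, the latter not past the threshold without white replicate 3 or any 1 brown library. Without white replicates 1, 2 and 3 there were 9, 10 and 4 ERF genes that rose, without brown replicates 2 and 3 there were 3 and 2, and without the trend 8. Without brown replicate 1 the list passed by camera (adjusted p = 0.0322, or adjusted p = 0.977 with an estimated correlation).

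Of 89 heat shock genes 9 were lower and 3 higher in brown husk, and 11 and 4 when adjusted over the list alone. The small heat shock proteins among them, a grouping made after the values were seen, had 6 of 22 members lower and 3 higher. The 18.5 kDa class I small heat shock protein (TRINITY_DN12897_c0_g1), a chaperone, fell from 221 ± 80.4 to 60.1 ± 9.34 TPM, a call lost without white replicate 3, brown replicate 1 or brown replicate 3. The 17.1 kDa class II protein (TRINITY_DN13399_c0_g1) fell from 68.5 ± 16.8 to 14.2 ± 1.27 TPM (log2 fold change -2.16 ± 0.21, limma adjusted p = 0.00233). A gene described as mediator subunit 37c, matched in Swiss-Prot to a heat shock cognate 70 kDa protein (TRINITY_DN16009_c2_g1), fell from 155 ± 77.5 to 16.3 ± 2.05 TPM. The list was below the other genes by camera (adjusted p = 5.5e-05) but not past the threshold with an estimated correlation (adjusted p = 0.942). The number that fell was 15 under TMM factors and under quantile normalization, 17 without white replicate 2 and 5 without white replicate 3 or brown replicate 3.

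**Figure D3:**
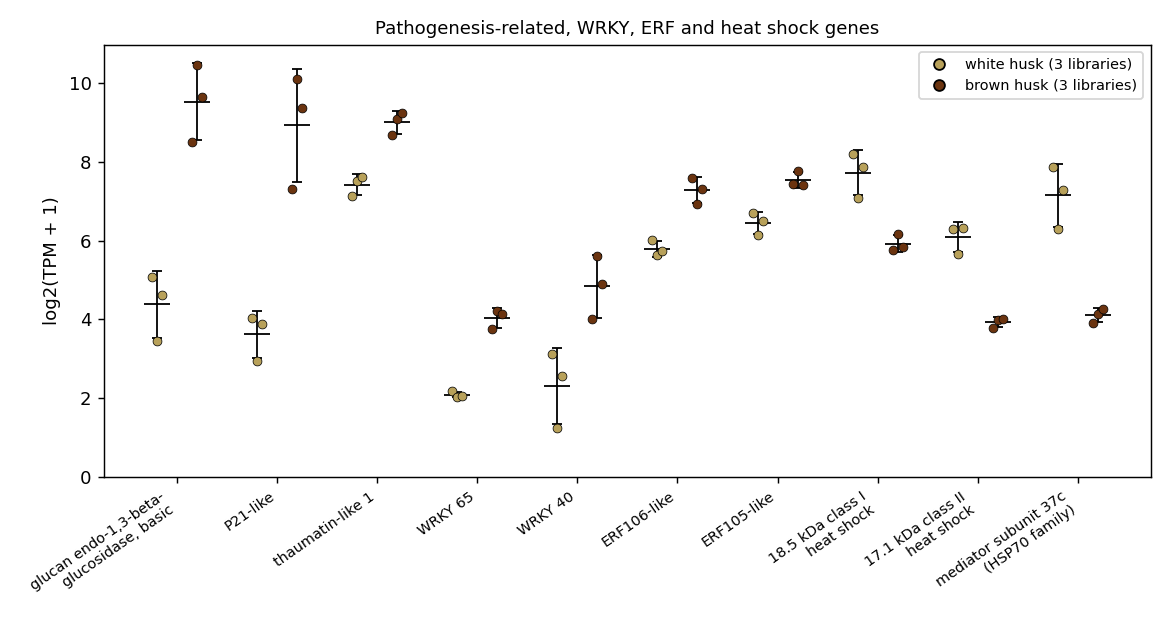
The vertical axis gives log2(TPM + 1) for 10 pathogenesis-related, WRKY, ERF and heat shock genes along the horizontal axis, with 1 point per library, tan for white and brown for brown husk, and bars for the mean and SD of the 3 log2 values. The first 7 genes lie higher in all 3 brown libraries and the last 3 lie lower.

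Markers of other tissues that a husk sample could hold were tested in the same way. Of 60 green tissue genes of photosystems and antennae none rose and 1 fell, with none of either when adjusted over the list alone. The fall was lost whichever library was left out, and 0 to 1 genes rose in those fits. That list was below the other genes by camera (adjusted p = 0.0278), not past the threshold with an estimated correlation (adjusted p = 0.942), under quantile normalization (adjusted p = 0.317), with array weights (adjusted p = 0.571), with a filter of 5 TPM (adjusted p = 0.119) or without white replicate 2 (adjusted p = 0.679) or brown replicate 2 (adjusted p = 0.755). Of 15 genes of secondary wall cellulose and fasciclins, markers of lignified shell, 1 rose and none fell (2 and 1 adjusted over the list alone). That rise was lost without white replicate 3, brown replicate 2 or brown replicate 3, and 0 to 2 genes rose over the 6 fits that left out 1 library. Of 94 cell cycle genes 3 rose and none fell, with none when adjusted over the list alone, and 2 fell under TMM factors and 3 under quantile normalization, while no cell cycle gene rose without any 1 brown library and 1 did without white replicate 1 or 3. Of 24 cuticle and wax genes 1 rose and 1 fell (6 and 2 adjusted over the list alone). Over the fits that left out 1 library 0 to 3 of these genes fell. The one that rose, a 3-ketoacyl-CoA synthase 2-like gene (TRINITY_DN12061_c3_g11), lost its call when any library other than brown replicate 1 was left out. The one that fell was an ABC transporter G family member 11-like gene (TRINITY_DN14775_c1_g1), with 333 ± 102 and 126 ± 18.8 TPM, a call lost without white replicate 3 or any 1 brown library. Of 4 kernel genes 1 rose and 2 fell (1 and 3 adjusted over the list alone), and as a set these were lower by fry (adjusted p = 0.0242). Their median log2 fold change was -1.13 and their mean -0.19, and under TMM factors and quantile normalization none rose and 3 fell. Oleosin 1-like (TRINITY_DN17035_c0_g1), an oil body protein, had 12.2 ± 2.02 and 5.06 ± 1.48 TPM, and its call was lost whichever library was left out. Without white replicate 1 or 2 there was 1 fall and no rise, without brown replicate 1 there were 1 rise and 1 fall, and without white replicate 3, brown replicate 2 or brown replicate 3 no kernel gene passed. The other kernel genes past the threshold are basic 7S globulin-like, and related proteins also occur outside seeds.

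The other lists held few changes or changes in both directions. Of 48 glutathione S-transferases 5 rose and 3 fell (5 and 4 adjusted over the list alone), and a probable member (TRINITY_DN11028_c0_g1) rose from 51.8 ± 5.93 to 225 ± 21.3 TPM in every leave-one-out fit. Of 36 lipoxygenase and jasmonate synthesis genes 2 rose and 3 fell (3 and 3), of 39 phospholipases 2 and 1 (7 and 2), of 17 ethylene synthesis genes 2 and 1 (4 and 1) and of 78 cell wall loosening genes 2 and 2 (7 and 3), the pairs in parentheses being adjusted over the list alone. A 13S-lipoxygenase 2-1-like gene (TRINITY_DN15544_c0_g1) fell from 9.72 ± 1.21 to 1.58 ± 0.510 TPM. None of 38 reactive oxygen scavenging, 8 ascorbate synthesis, 14 JAZ/TIFY and 39 MATE and vacuolar transporter genes passed by limma, with 7, 2, 3 and 6 at an unadjusted p under 0.05, and over the lists alone 1 JAZ/TIFY gene was higher and 1 lower. Under TMM factors 1 scavenging gene and 1 transporter rose and 1 transporter fell. Of 117 MYB factors 8 rose and 3 fell (12 and 6 adjusted over the list alone), which became 6 and 6 under TMM factors and 5 and 7 under quantile normalization. Of 61 NAC factors 5 rose and 1 fell (6 and 1 adjusted over the list alone), and of 132 retrotransposon and transposon genes 10 rose and 2 fell (15 and 6 adjusted over the list alone). A Copia-type gene (TRINITY_DN13235_c0_g5) had 0.223 ± 0.178 and 35.7 ± 2.17 TPM. Of 270 cytosolic ribosomal protein genes 2 rose and 9 fell (2 and 6 adjusted over the list alone). The 60S protein L32-1 gene (TRINITY_DN13032_c3_g3) rose from 30.2 ± 7.39 to 425 ± 115 TPM and a 40S protein S16-like gene (TRINITY_DN13882_c2_g1) fell from 595 ± 190 to 118 ± 37.7 TPM, both members of families with near-identical copies. Of 46 reference genes 3 fell and none rose (6 and 4 adjusted over the list alone), all 3 alpha tubulins. Alpha tubulin 1 (TRINITY_DN13008_c0_g1) fell from 2082 ± 650 to 751 ± 90.1 TPM, a call lost without white replicate 3 or any 1 brown library. Leaving out 1 library moved these counts. Retrotransposon and transposon rises numbered 4 and 1 without white replicates 1 and 3 and 2, 1 and 3 without brown replicates 1, 2 and 3. NAC rises numbered 2 without white replicate 3, 3 without brown replicate 1 and none without brown replicate 2 or 3. MYB rises and falls were 5 and 3, 6 and 5, and 2 and 0 without white replicates 1, 2 and 3, and 2 and 1 without brown replicate 2 or 3. Glutathione S-transferases gave 2 rises and 1 fall without white replicate 3, brown replicate 2 or brown replicate 3. Ribosomal protein falls numbered 5 without white replicate 3, brown replicate 1 or brown replicate 2 and 4 without brown replicate 3, and no reference gene fell without white replicate 3 or any 1 brown library. Over the 6 fits, 0 to 3 lipoxygenase and jasmonate genes, 0 to 2 phospholipases, 0 to 1 ethylene synthesis genes and 0 to 5 cell wall loosening genes rose, with fewest without white replicate 3, brown replicate 2 or brown replicate 3. Lipoxygenase and jasmonate falls numbered 3 without white replicate 2 and 1 without any other 1 library. Cell wall loosening falls numbered 3 and 4 without white replicates 1 and 2 and none without white replicate 3 or any 1 brown library, phospholipase falls 2 without white replicate 2 and none without any other 1 library, and ethylene synthesis falls none without white replicate 3 or brown replicate 3. Membership by both descriptions in place of either, an alternative chosen after seeing the data, left 12 retrotransposon and transposon genes with no rise and no fall by limma (1 at an unadjusted p under 0.05). It left 2 rises and 1 fall of glutathione S-transferases, no rise of lipoxygenase and jasmonate genes, 3 rises of NAC factors and 1 fall of reference genes, and it also removed from their lists the shikimate gene that rose, the green tissue gene that fell, 1 of the lignin branch falls and 1 of the kernel falls. No list named in this paragraph was past the threshold by camera, though reference genes were below the other genes under TMM factors (adjusted p = 0.0476) and without white replicate 2 (adjusted p = 0.0302) or brown replicate 3 (adjusted p = 0.0108), and ribosomal protein genes without white replicate 1 (adjusted p = 0.00347) or white replicate 3 (adjusted p = 0.0093). With an estimated correlation none of these 5 calls held (adjusted p of 0.907 to 0.993).

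**Figure D4:**
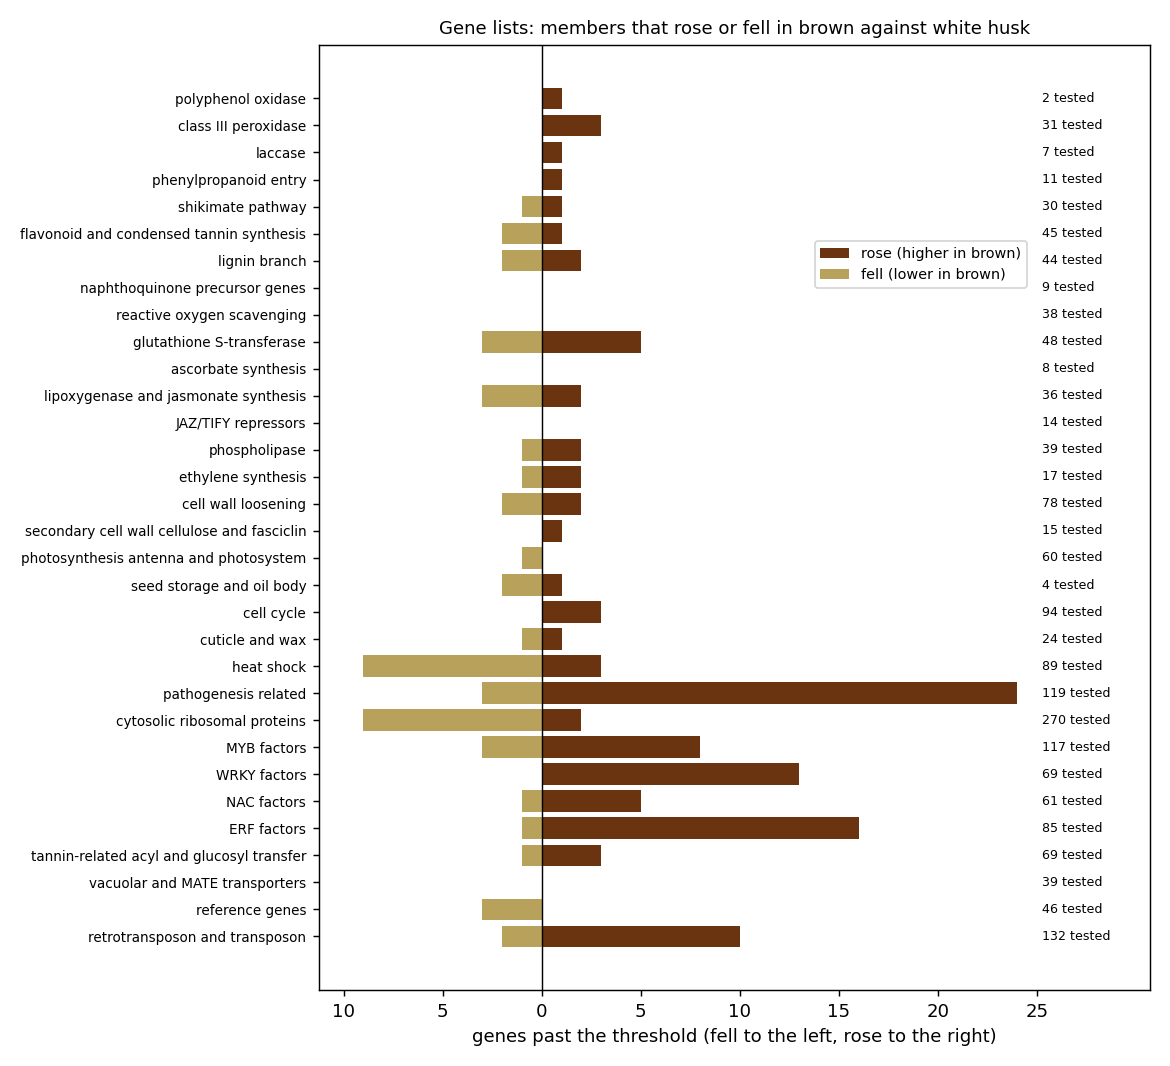
Bars give the number of genes past the threshold in each of the 32 gene lists, with those that rose to the right and those that fell to the left of 0, and the number tested at the right edge. Pathogenesis-related genes (24), ERF factors (16) and WRKY factors (13) have the most rises, and heat shock (9) and cytosolic ribosomal proteins (9) the most falls. Counts are not scaled to list size, and 89 heat shock genes were tested against 270 for cytosolic ribosomal proteins.

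Terms for defence, chitin, ethylene signalling and wounding were enriched among genes higher in brown husk, and terms for heat and light stress among genes lower in it. Among higher genes 29 GO terms and 1 KEGG pathway were enriched, and among lower genes 3 GO terms and no KEGG pathway (one-sided Fisher's exact test, Benjamini-Hochberg). Defense response covered 60 of the 745 higher genes with a GO term, out of 480 such genes among 18973 tested (adjusted p = 1.9e-12). Response to chitin covered 24 out of 95 (adjusted p = 9.8e-11), chitinase activity 9 out of 26 (adjusted p = 0.000101), the ethylene-activated signaling pathway 20 out of 147 (adjusted p = 0.000237) and response to wounding 20 out of 155 (adjusted p = 0.000469). Acid phosphatase activity covered 8 out of 36 (adjusted p = 0.00494) and ADP binding, a property of many resistance proteins, 18 out of 150 (adjusted p = 0.00232). The KEGG pathway was amino sugar and nucleotide sugar metabolism, with 42 out of 417 genes (adjusted p = 5.4e-05). The terms among lower genes were response to heat, with 17 out of 134 (adjusted p = 2.1e-05), response to high light intensity, with 9 out of 47 (adjusted p = 0.000736), and response to hydrogen peroxide, with 7 out of 47 (adjusted p = 0.0409). Terms share genes and are not independent. Fisher's exact test also treats genes as independent of each other, so its p-values do not measure the spread between samples. Genes can vary together, with an estimated correlation of 0.25 in the pathogenesis-related list and 0.36 in the WRKY list. The number among higher genes was 10 without white replicate 3, 14 without brown replicate 2, 4 without brown replicate 3 and 18 without the trend, and that among lower genes was 1 without brown replicate 1 and 5 under TMM factors.

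Some assembled genes were listed only on one side. At 0 TPM in all 3 white libraries and at 1 TPM or more in all 3 brown libraries stood 319 genes, and 187 were the other way round. The other 9 splits of the libraries into 3 against 3 gave 23 to 46 such genes in both directions together, against 506 here. Of the 319 genes 149 had a mean of at least 5 TPM in brown husk and 153 had a description in the main annotation column, and of the 187 genes 76 and 92 did so in white husk. A description that names a protein was held by 95 of the 319 and 62 of the 187. In 26 and 15 of these it contained the words resistance protein, receptor-like or receptor kinase. Without white replicate 1 or white replicate 3 the first count was 543 and 557.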

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

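Leaving out the second library of both groups, matching in both descriptions, the WRKY list without disease resistance proteins and the 4 added lists were chosen after seeing the data. Every gene past the threshold kept its sign in each alternative that tested it. Since all alternatives reuse libraries on which these genes were selected, a kept sign says little about stability. Across the alternatives that leave out 1 library, higher genes numbered 410 to 1255 and lower genes 259 to 1013, lists by camera 1 to 5 higher and 1 to 3 lower, and terms 4 to 42 among higher and 1 to 4 among lower genes. Fewer samples enter those fits, and no other cause was tested. Across the same alternatives the genes at 0 in white husk numbered 332 to 557, those at 0 in brown husk 197 to 274, and the difference in the share of the 100 highest genes ran from -4.28 to 0.344 percentage points, positive only without white replicate 2. Without both second libraries 561 genes were higher, 476 lower, 1 list was lower and 8 terms were enriched among higher genes. In that fit the mean log2 fold change of green tissue genes was 0.16, above the other genes in place of below them. Quantile normalization gave 1275 lower genes, 1 lower list and 5 terms among lower genes, and TMM factors also gave 5 such terms. The filter of 5 TPM tested 16426 genes and gave 2 higher lists, 1 lower list and 5 terms among lower genes. Array weights gave 1 lower list, the fit without trend 18 terms among higher genes, and the fold of at least 2 left 1 term among lower genes. With an estimated correlation 0 lists were higher and 0 lower, and with fry likewise 0 and 0 of the lists tested by camera, and at an unadjusted p under 0.05 the first gave 0 and camera 5. Matching in both descriptions gave 2 higher lists, the second being pathogenesis-related genes (adjusted p = 0.0401, or adjusted p = 0.975 with an estimated correlation). The WRKY list without disease resistance proteins had 66 tested members, of which 13 were higher and 0 lower (adjusted p = 5.5e-05, or adjusted p = 0.942 with an estimated correlation). Requiring 5 TPM in the other group left 55 genes at 0 in white and 34 at 0 in brown husk. For settings other than those that test fewer genes or samples the cause was not tested.

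Whether replicate numbers pair the samples is undecided. Deviations from the group means correlated at 0.0572, 0.0561 and 0.0109 between libraries of the same number, all under 0.1. Each library nevertheless correlated best with its own number, a hint from the data and not from the design. With the replicate number as a block 735 genes were higher and 490 lower, and 17 terms were enriched among higher genes. Among named genes, 1091 values over all alternatives stayed on the same side of the threshold, 376 were no longer past it, 5 newly passed it and none past it changed direction. Of the 1091, 6 values of 2 genes that were not past it, cinnamate 4-hydroxylase and laccase-14-like, had the other sign. Among gene lists 524 values stayed on the same side, 5 were no longer past it, 12 newly passed it and 1 past it changed direction, the green tissue value above. Of the 524, 30 values of 11 lists, not past it in either fit, lay in the other direction by camera, among them cytosolic ribosomal proteins, NAC factors and flavonoid synthesis. Read depth is unknown, so its effect on low genes could not be measured.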

Other observations

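The lists of phosphate starvation genes, receptor-like kinases, resistance proteins and MADS-box factors, the tests of white replicate 2, of other tissue and of Swiss-Prot sources were chosen only after the results were seen. For these 4 lists, camera and fry p-values were adjusted over the 4 alone. Those of the 30 lists written before and tested by camera were adjusted over more lists, so the 2 sets of adjusted p-values are not comparable. Of 66 tested genes of the phosphate starvation response 24 were higher in brown husk and none lower (camera adjusted p = 8.1e-10, or 0.217 with an estimated correlation), with 25 under TMM factors and 24 under quantile normalization (adjusted p = 0.0252 and 0.00898 with an estimated correlation). The number was 11 without white replicate 3, 12 without brown replicate 2 and 11 without brown replicate 3, and fry gave an adjusted p of 0.00822. SPX domain proteins, which sense phosphate status, went from 3.11 ± 1.95 to 78.0 ± 1.88 TPM for SPX 2-like (TRINITY_DN12208_c0_g2, with 1 member of its assembly cluster past the threshold in the opposite direction, log2 fold change 4.41 ± 0.38, limma adjusted p = 0.00159) and from 9.38 ± 0.601 to 117 ± 27.5 TPM for SPX 3-like (TRINITY_DN13421_c0_g2) (SD, n = 3 each). Purple acid phosphatase 17-like (TRINITY_DN9194_c0_g1), which frees phosphate from organic compounds, went from 11.7 ± 1.42 to 147 ± 26.3 TPM, and the glycerophosphodiester phosphodiesterase GDPD1-like (TRINITY_DN13219_c1_g1) from 31.4 ± 9.32 to 320 ± 13.7 TPM. A putative glycerol-3-phosphate transporter 1 (TRINITY_DN13204_c1_g6) went from 9.12 ± 2.64 to 53.3 ± 6.87 TPM. Since genes of this kind prompted the list, its test is not independent of the observation, and phosphate content was not measured in the data used here.

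Receptor-like kinases had 77 of 680 members higher and 21 lower (camera adjusted p = 0.000434, or 0.676 with an estimated correlation), and 25, 41, 31 and 23 were higher without white replicate 3 and brown replicates 1, 2 and 3, and 12 lower without brown replicate 3. Disease resistance proteins went both ways, with 39 of 312 higher and 25 lower (camera adjusted p = 0.131, or 0.735 with an estimated correlation). Under TMM factors 41 were higher and 33 lower (adjusted p = 0.0485, or 0.359 with an estimated correlation), and the filter of 5 TPM gave 28 and 9 (adjusted p = 0.00246, or 0.50 with an estimated correlation). The counts were 34 and 10 without white replicate 1, 21 and 7 without white replicate 3, and 27 and 10, 24 and 9, and 18 and 7 without brown replicates 1, 2 and 3. Of 32 MADS-box factors 3 were lower and none higher (camera adjusted p = 0.000434, or 0.217 with an estimated correlation), with 8 lower under TMM factors and under quantile normalization (adjusted p = 0.0252 and 0.0407 with an estimated correlation). Without white replicate 2 there were 6 lower and 1 higher, without white replicate 1 or brown replicate 2 there was 1 lower, and without white replicate 3 or brown replicate 3 none passed. Besides the AGL9-like gene these were ANR1-like (TRINITY_DN14337_c0_g4), with 9.82 ± 0.290 and 3.71 ± 0.752 TPM, and AGL42-like (TRINITY_DN6378_c0_g1), with 6.60 ± 2.83 and 0.81 ± 0.703 TPM. Genes without a main description took 13.3%, 12.5% and 12.9% of TPM in white and 16.2%, 15.6% and 15.7% in brown husk (exact two-sided permutation p = 0.1, the smallest that 3 against 3 can give). Genes without a main description whose Swiss-Prot match is from a mammal numbered 15 and summed to 108, 78.8 and 29.3 TPM in the white and 29.1, 90.1 and 139 TPM in the brown libraries.

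More genes were higher than lower in brown husk, 63.9% of those past the threshold. With TMM factors the share was 51.9% and with quantile normalization 49.7%, but both centre the fold changes and so balance the directions whatever the cause. The range of 45% to 55% set in advance for an effect of library composition therefore decides nothing, and composition in the TPM scaling cannot be told apart from a difference in expression. White replicate 2, whose TMM factor of 0.753 was the lowest, may carry part of this, since without it the share was 55.3%, between the ranges set for and against it, so that explanation stays open. A difference between varieties in how many genes husk expresses was not tested apart from these.

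Of 119 pathogenesis-related genes 24 were higher in brown husk, and the mean log2 fold change of the list, which was not past the threshold by camera (adjusted p = 0.119), was 0.51 above that of all genes. The excess in the mean did not come from brown replicate 2 alone, since it was 0.41 without that library. The list was then still not past the threshold by camera (adjusted p = 0.208, unadjusted p = 0.0277), and 11 in place of 24 members passed. With an estimated correlation it was not past it with all libraries either (camera adjusted p = 0.942). How much of the pattern that library carries therefore stays undecided. Microbial reads counted as these genes could not be decided. Of the higher members 24 of 24 had a Swiss-Prot match from an organism other than a microbe, while 498 of the listed genes match a microbe. Members were picked by the text of their descriptions, and microbes were recognized only by a set of name fragments. The matches may thus follow from how the list was made. The planned test used only 6 genes with a microbial match and no main description, which summed to 146 to 223 TPM in the white and 131 to 234 TPM in the brown libraries, and neither result speaks to whether microbes were on the fruit. Other tissue in the brown samples cannot be told apart, because among the green, shell, epidermis and dividing tissue lists the largest deviation of a median from all genes was -0.28, for green tissue (the 4 kernel genes, left out of this test, had a median of -1.13, lower in brown husk), and these markers already stood at medians of 4.21 to 64.7 TPM in white husk, where a small admixture would be hidden, and a difference between the varieties in defence, ripening or infection stays a hypothesis that was not tested.

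Genes listed at 0 in one group numbered 506. Low sampling near the detection limit that varies only between single libraries is argued against, since the highest of the other 9 splits gave 46. Those splits mix the groups and cannot show a depth difference that follows them, and depth is unknown, so that possibility stays open. Genes at 0 TPM numbered 2017, 3603 and 1934 in the white and 1933, 1382 and 1265 in the brown libraries. Median length was 282 for genes at 0 in white and 312 for those at 0 in brown husk, against 549 for all listed genes. An assembly that splits alleles or paralogs into separate genes may account for part, since 14.6% of these genes had a partner in the same assembly cluster past the threshold in the opposite direction, as many as only 2 of 1000 matched random sets had (median 9.88%, highest 15.6%). The random sets were matched on mean TPM and length but not on the number of genes in a cluster. A difference in cluster size could thus also give the excess. Of the 1797 genes past the threshold and not in these sets 12.3% had such a partner, so part of the excess over random genes may be shared by genes past the threshold in general. The 14.6% lies inside the range that was set in advance as speaking against this, but so near its top that the bound was too wide to decide, and alleles placed in different clusters are not seen, so sequence differences between the varieties stay open beside differences in expression.

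With 10 splits of the 6 libraries into 3 against 3, the share of splits with a result as large is never under 0.1, too few to test chance. The real split gave 2269 genes past the threshold and the highest of the other splits 0, so 1 of the 10 splits gave as many. For genes with a fitted fold of at least 2 the real count was 1989 and the highest other 0 (1 split as large), and for annotation terms 33 and 0 (1 split as large). For lists by camera the real split gave 3 and the highest other, white replicate 1 with brown replicates 2 and 3 against the rest, gave 9, and 8 of the 10 splits gave at least 3. Camera with a preset correlation thus called lists between mixed groups of libraries as well. Genes of a list varying together between single libraries could give such calls. The mixed groups also hold unequal numbers of white and brown libraries, so part of the difference between varieties remains in them. These possibilities were not told apart.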
